A study of Homo sapiens with 6 samples.

How the data were processed

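RNA sequencing was made from 6 samples of OVCAR8, an established human ovarian cancer cell line, collected 4 days after treatment with virus. Per the labels, 3 samples received the vector called shEV and 3 had a knockdown of FAP. FAP encodes fibroblast activation protein, a cell surface serine protease that cleaves after proline. Per the labels' protocols, libraries were made from total RNA with a SMARTER mRNA kit. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

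The values used come from 1 table of the authors' comparison of the 2 groups, with 28395 genes named by NCBI Gene number. Per the submitters' processing notes, reads were aligned with STAR and tested with DESeq2; their versions, the counting tool, the genome build and the annotation are not given in the sources used here. Per the file headers, the authors deposited for each gene a mean normalized count, which is a signal averaged over all samples after division by size factors. The deposited table also holds the log2 fold change and its standard error, both on the log2 scale. The deposited Wald score is the log2 fold change divided by its standard error, and the deposited p-value and adjusted p-value are those of a Wald test with Benjamini-Hochberg adjustment, per the file headers. Values per sample were not analysed here. So no mean and SD per group, no fit of another model, and no sample left out could be computed, and the design's test of count tables was replaced by the authors' deposited test, as the design foresaw.

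The file headers do not state which group is the numerator of the fold change. FAP itself was to give the only orientation, and its 2 reads, on the side that gives negative fold changes, were too few for that. Directions are therefore given as positive and negative deposited log2 fold changes, and not as higher or lower in FAP knockdown. If FAP knockdown is the numerator, positive values mean higher in FAP knockdown; this is an assumption that the table does not settle.

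The deposited fold changes have the form of shrunken estimates. Their standard errors never exceed 0.462, peak at middle means and fall to a median of 0.199 at means of 1 or less, as with a prior centred on 0 whose SD is 0.925. Fold changes of low genes are thus understated, and Wald scores and p-values are those deposited. The deposited score was checked against the fold change over its standard error, and the adjusted p against Benjamini-Hochberg over the 18331 genes that have one. A p-value without an adjusted p was listed for 3304 genes, all with means of 1.98 or less.

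Depth per sample is not in the table. Genes with reads in 1 library give means that are whole multiples of what 1 read is worth there, and these steps gave 6 relative size factors without sample names. They ranged from 0.925 to 1.26 on the side of the 3 libraries whose reads give positive fold changes and from 0.808 to 1.03 on the other, a range of 1.56 times from lowest to highest. The mean normalized counts sum to 35170089. A floor of 3 counts was used for statements on absence, and counting error alone is covered by it.

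A gene was called when its deposited adjusted p was under 0.05, and called at least 2-fold when its absolute log2 fold change was also 1 or more. Before the data were examined, 40 gene lists, the tests, the alternatives and a rule for naming genes were fixed. The rule takes FAP; the 12 largest positive and 12 largest negative changes among called genes with a mean normalized count of at least 100 and a gene symbol; the 5 smallest adjusted p in each direction under the same filter; up to 4 members with the smallest adjusted p for each list with a called member, and for other lists up to 2 members with the highest mean count; and DPP4, ITGB1, CDH1, CDH2, VIM and FN1. Some genes the rule takes are not reported here. Each list with at least 5 tested members was tested against all other genes with limma's cameraPR on the deposited Wald scores, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 38 lists. Each list median was also set against 10000 random lists of the same size matched on mean count, as a description. The random lists could draw any tested gene of like mean count, including members of this or other lists such as ribosomal protein genes. An estimated correlation needs values per sample and could not be had. Symbols came from a RefSeq gene table used for names only, which matched 27745 gene numbers, 97.7% of the table.

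For GC content, length and 3' UTR sequence, the protein-coding transcript with the longest coding part was taken for each gene from GENCODE 29. It was found for 84.3% of the tested genes. Trends of the fold change were fitted by local regression over 0.3 of the genes at a time. The heptamer test covered the 11421 genes with a mean normalized count of at least 100 and a 3' UTR of at least 50 bases. Associations of each of the 3' UTR heptamers (words of 7 bases) held by at least 50 genes were computed on fold changes bounded at 2. This was done after linear terms for length and base composition, and the associations were set against 100 shuffles of the genes. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.

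The steps were tested on simulated data. With 200 of 18331 genes changed and the deposited standard errors, 26.9% of genes changed by 0.5 on the log2 scale were called, 71.2% of those changed by 1 and 98.5% of those changed by 2, with 6 false calls. These shares and false calls take the deposited standard errors as correct, so they cannot show whether those errors suit so few samples. The simulated changes were not shrunken, and far fewer genes were changed than the 7267 called in the data. The adjustment depends on that number, so the shares do not carry over to the data. A shifted list was called with 0 of the other lists, and a planted heptamer ranked first. Both used random values independent between genes and without a trend on base composition. They therefore cannot show how often lists of correlated genes are falsely called, or whether base composition misleads the heptamer test. Alternatives covered the threshold, the adjustment, filters on the mean count, a t distribution with 4 degrees of freedom, centring, the size threshold, and the statistic, correlation and members of the list test.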

Results

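The question put by the series' title and labels is how depletion of FAP changes gene expression in OVCAR8 ovarian cancer cells 4 days after virus. The data were 3 shEV samples and 3 FAP knockdown samples, compared gene by gene in the authors' deposited table. The table does not name the numerator, so changes are given as positive or negative.

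FAP, the targeted gene, is listed in the authors' deposited table with a mean normalized count of 0.323, which matches exactly 2 reads in 1 of the 6 libraries and 0 in the other 5. This lies under the floor of 3 counts, so no fold is given. Among genes with reads in 1 library, 2 reads were more frequent than 1 (725 genes against 473), so 2 reads need not be 2 fragments. The deposited p of FAP was 0.603 and no adjusted p was listed. FAP mRNA was thus under the floor in both groups, while the mean normalized counts of all genes summed to 35170089. Depletion of FAP was therefore not detectable, and the labels could not be checked against the targeted gene.

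CCN2, a secreted matricellular protein, had the smallest adjusted p in the authors' deposited table, with a log2 fold change of 3.54 ± 0.11 (standard error, mean normalized count 5756, adjusted p = 1.1e-231 by the Wald test of DESeq2). The other large positive values in the authors' deposited table were those of GGT5 (4.39 ± 0.34), the integrin subunit gene ITGB3 (3.46 ± 0.22), ITIH3 (3.20 ± 0.24), LAPTM5 (3.16 ± 0.30), the receptor kinase gene ROR1 (3.16 ± 0.27) and the water channel gene AQP1 (2.91 ± 0.24). CYP11A1, which makes pregnenolone from cholesterol, stood at 2.77 ± 0.26, and CPT1A, which brings fatty acids into mitochondria, at 2.61 ± 0.16 in the authors' deposited table. APOL3, AGT, FOS, IL11 and ENC1 completed the positive genes named for their size or smallest adjusted p in the authors' deposited table, with log2 fold changes of 2.64, 2.61, 2.58, 2.52 and 1.90.

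TXNIP, a thioredoxin-binding protein, had the largest negative value among the named genes in the authors' deposited table, −4.49 ± 0.33 (adjusted p = 1.4e-38). CYB5R3, a cytochrome b5 reductase, followed at −3.65 ± 0.12 (adjusted p = 3.8e-202 in the authors' deposited table). The circadian transcription factor gene DBP was at −3.30 ± 0.21, the caveolar ATPase gene EHD2 at −3.21 ± 0.12 and SHISA5 at −2.95 ± 0.13 in the authors' deposited table. C1QL1, TEX19, HCN2, MYBL2, BTBD2, FNDC10 and the kinase gene PAK4 had values from −2.76 to −2.43 in the authors' deposited table. Of the 12 largest negative genes 8 hold the word ACGCCC in the 3' UTR, and 2 of the 12 largest positive genes do. This word was chosen after these same values were seen, and 9.76% of the 11421 genes in the heptamer test hold it. Lengths of the 3' UTRs were not matched. TGFBI, a secreted matrix protein with a mean normalized count of 40143, was at −2.04 ± 0.10 in the authors' deposited table.

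Of 18331 genes with an adjusted p in the authors' deposited table, 7267 (39.6%) were called, 3640 with positive and 3627 with negative values. Of these, 1903 changed at least 2-fold, 1012 positive and 891 negative, and 175 at least 4-fold, 117 positive and 58 negative. Called genes changed at least 2-fold had a median mean normalized count of 92.0 on the positive side and 659 on the negative side. With a t distribution of 4 degrees of freedom in place of the normal, 1336 genes were called. Among the 11880 genes with a transcript and a mean normalized count of at least 100, log2 fold changes were related to transcript GC content (Spearman rho −0.36) and length (0.31). Genes are not independent replicates.

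**Figure D1:**
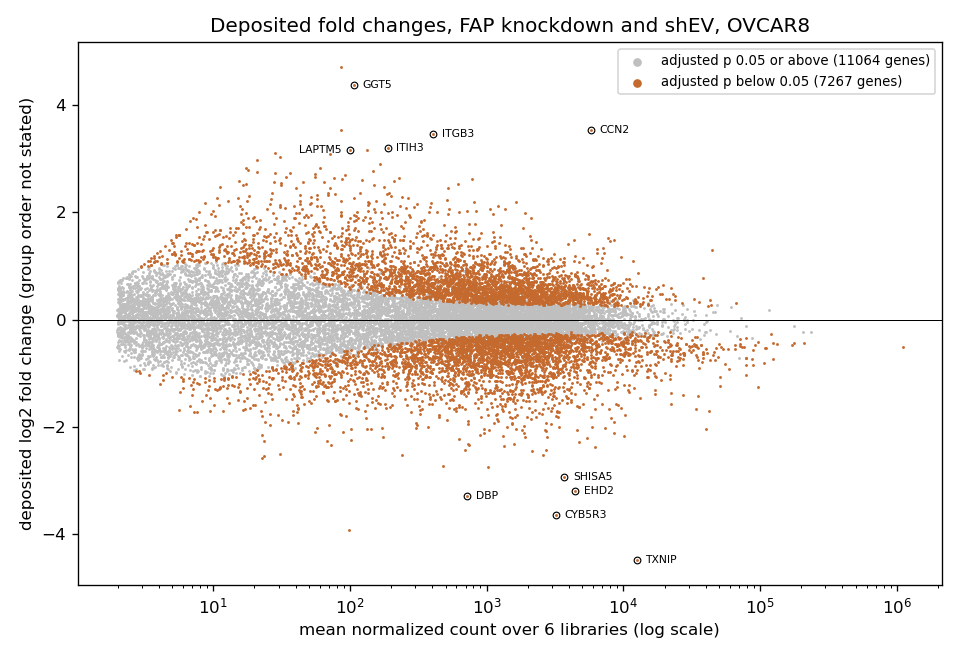
Deposited log2 fold change (vertical axis) against mean normalized count (horizontal axis, log scale) for the 18331 tested genes, 1 point per gene. The 7267 called genes are orange and the others grey, and 5 named genes per direction are circled, from TXNIP at −4.49 to GGT5 at 4.39.

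Genes of cytokine signalling and NF-kappaB moved to the positive side. Of 23 tested members, 20 were called positive and 0 negative (20 and 0 adjusted over the list alone; list test adjusted p = 4.2e-08, median log2 fold change 0.84). IL11 was at 2.52 ± 0.16, IL6 at 1.77 ± 0.21, TRAF1 at 1.69 ± 0.18 and the neutrophil chemokine gene CXCL5 at 0.95 ± 0.16 in the authors' deposited table.

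Interferon response genes were also mostly positive, 25 of 33 tested against 4 negative (25 and 4 adjusted over the list alone; list test adjusted p = 5.6e-10). IFIT2 was at 2.46 ± 0.19, IFIT3 at 2.19 ± 0.15, OASL at 2.03 ± 0.14 and DDX60 at 1.99 ± 0.15 in the authors' deposited table. Of 7 tested leukocyte markers 1, CD14 (0.80 ± 0.19 in the authors' deposited table), was called positive and 1, CD68 (−0.49 ± 0.11), negative. Endothelial markers gave 5 positive and 1 negative of 10, with KDR at 1.82 ± 0.23 and EGFL7 at −1.25 ± 0.14 in the authors' deposited table. Fibroblast markers gave 2 positive and 3 negative of 11, and 0 of 2 tested erythroid markers were called.

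Immediate early genes, the fast transcriptional targets of growth factor signalling, were called positive in 17 of 25 and negative in 3 (18 and 4 adjusted over the list alone; list test adjusted p = 9.4e-08). FOS was at 2.58 ± 0.22, the signalling inhibitor gene SPRY4 at 2.03 ± 0.15 and ETV5 at 1.72 ± 0.13, and JUND went the other way at −1.82 ± 0.16 in the authors' deposited table.

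Ribosomal protein genes were called negative in 72 of 79 and positive in 0 (72 and 0 adjusted over the list alone; list test adjusted p = 8.8e-13, median −0.63). RPL41 was at −1.70 ± 0.18, RPLP1 at −1.43 ± 0.17, RPLP0 at −1.26 ± 0.15 and RPL28 at −0.84 ± 0.15 in the authors' deposited table. These genes have many processed pseudogenes, and how reads shared between copies were counted is not given in the sources used here.

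Genes of caveolae and the actin cytoskeleton were called negative in 13 of 22 and positive in 0 (13 and 0 adjusted over the list alone; list test adjusted p = 4.3e-06). TAGLN was at −1.67 ± 0.14, PDLIM7 at −1.24 ± 0.12, CAVIN1 at −0.92 ± 0.11 and CNN2 at −0.85 ± 0.11 in the authors' deposited table. Focal adhesion and invadopodia genes gave 12 negative and 4 positive of 26 (12 and 4 adjusted over the list alone; list test adjusted p = 0.0019). ZYX was at −2.37 ± 0.12, the actin bundler gene FSCN1 at −2.18 ± 0.11 and PXN at −1.58 ± 0.11, and PARVA at 0.77 ± 0.11 in the authors' deposited table. The adjusted p of this list reached 0.10 among the alternatives, and its median lay at percentile 10.3 of 10000 random lists matched on mean count.

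Mesenchymal state genes were called negative in 11 of 18 and positive in 2 (11 and 2 adjusted over the list alone; list test adjusted p = 0.027, up to 0.12 among the alternatives). VIM, the intermediate filament vimentin, was at −1.25 ± 0.13, and ZEB2 (1.01 ± 0.17) and SPARC (0.78 ± 0.10) were the 2 positive members in the authors' deposited table. FN1, fibronectin, was at −1.03 ± 0.18 in the authors' deposited table. Epithelial state genes gave 8 negative and 0 positive of 21 (8 and 0 adjusted over the list alone; list test adjusted p = 0.046, up to 0.19 among the alternatives; median at percentile 15.8 of matched random lists), with KRT18 at −1.12 ± 0.13 and EPCAM at −0.89 ± 0.15 in the authors' deposited table. The cadherin genes CDH1 (0.50 ± 0.27, adjusted p = 0.12) and CDH2 (0.06 ± 0.12, adjusted p = 0.72), the integrin subunit gene ITGB1 (−0.01 ± 0.13, adjusted p = 0.95) and DPP4 (0.68 ± 0.32, adjusted p = 0.078), a protease related to FAP, were not called in the authors' deposited table.

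Integrin genes were positive in 10 of 19 and negative in 3 (12 and 3 adjusted over the list alone; list test adjusted p = 0.0051, up to 0.052 among the alternatives). ITGB3 led, ITGA11 was at 1.82 ± 0.24, ITGA7 at 1.33 ± 0.13 and ITGB4 at −1.07 ± 0.14 in the authors' deposited table. Prolyl peptidases, the family of FAP, gave 2 positive and 2 negative of 7 (4 and 2 adjusted over the list alone).

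Genes of lipid metabolism were called positive more than negative. Cholesterol synthesis gave 10 positive and 4 negative of 25 (10 and 4 adjusted over the list alone; list test adjusted p = 0.0054, up to 0.14 among the alternatives), with INSIG1 at 1.59 ± 0.16 and HMGCS1 at 1.07 ± 0.11 in the authors' deposited table. Fatty acid metabolism gave 12 positive and 4 negative of 25 (12 and 5 adjusted over the list alone; list test adjusted p = 0.0038, up to 0.073), led by CPT1A and by ELOVL6 at 1.57 ± 0.15 in the authors' deposited table. Apoptosis regulators gave 13 positive and 3 negative of 25 (13 and 3 adjusted over the list alone; list test adjusted p = 0.038, up to 0.19), including PMAIP1 at 1.15 ± 0.15 in the authors' deposited table.

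Glycolysis gave 11 negative and 3 positive of 21 (11 and 4 adjusted over the list alone; list test adjusted p = 0.0082, up to 0.079 among the alternatives; median at percentile 46.7 of matched random lists, so no lower than that of equally abundant genes), with ALDOA at −1.66 ± 0.13 in the authors' deposited table. Oxidative phosphorylation gave 11 negative and 1 positive of 40 (8 and 1 adjusted over the list alone; list test adjusted p = 0.033, up to 0.19), with NDUFA8 at −1.53 ± 0.15 in the authors' deposited table.

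The list test called 14 of 38 lists, and it compares a list with all other genes whatever their abundance. Against 10000 random lists matched on mean count, the medians of NF-kappaB and cytokine, interferon and immediate early genes lay at percentile 100, integrins at 99.99, fatty acid metabolism at 99.98, apoptosis regulators at 99.3 and cholesterol synthesis at 98.4. Ribosomal proteins lay at percentile 0, mesenchymal state genes at 0.090, caveolae and actin at 0.98 and oxidative phosphorylation at 1.63. Lists that were not called reached similar percentiles: ovarian cancer and Mullerian genes 0.28, matrix proteases and inhibitors 99.6 and stem cell markers 99.2. Among the lists it did not call, TGF-beta targets, which hold CCN2 at the positive end and TGFB1 at −2.28 ± 0.13 in the authors' deposited table, gave 7 positive and 8 negative of 21. YAP and TAZ targets gave 6 and 8 of 22, collagens 9 and 4 of 23, and matrix proteases and inhibitors 13 and 10 of 30, with MMP9 at 1.98 ± 0.15 and MMP15 at −1.35 ± 0.12 in the authors' deposited table. DNA replication genes gave 5 positive and 4 negative of 26, and mitosis 1 and 6 of 25. Ovarian cancer and Mullerian genes gave 0 positive and 4 negative of 8, with PAX8 at −0.68 ± 0.13 in the authors' deposited table.

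**Figure D2:**
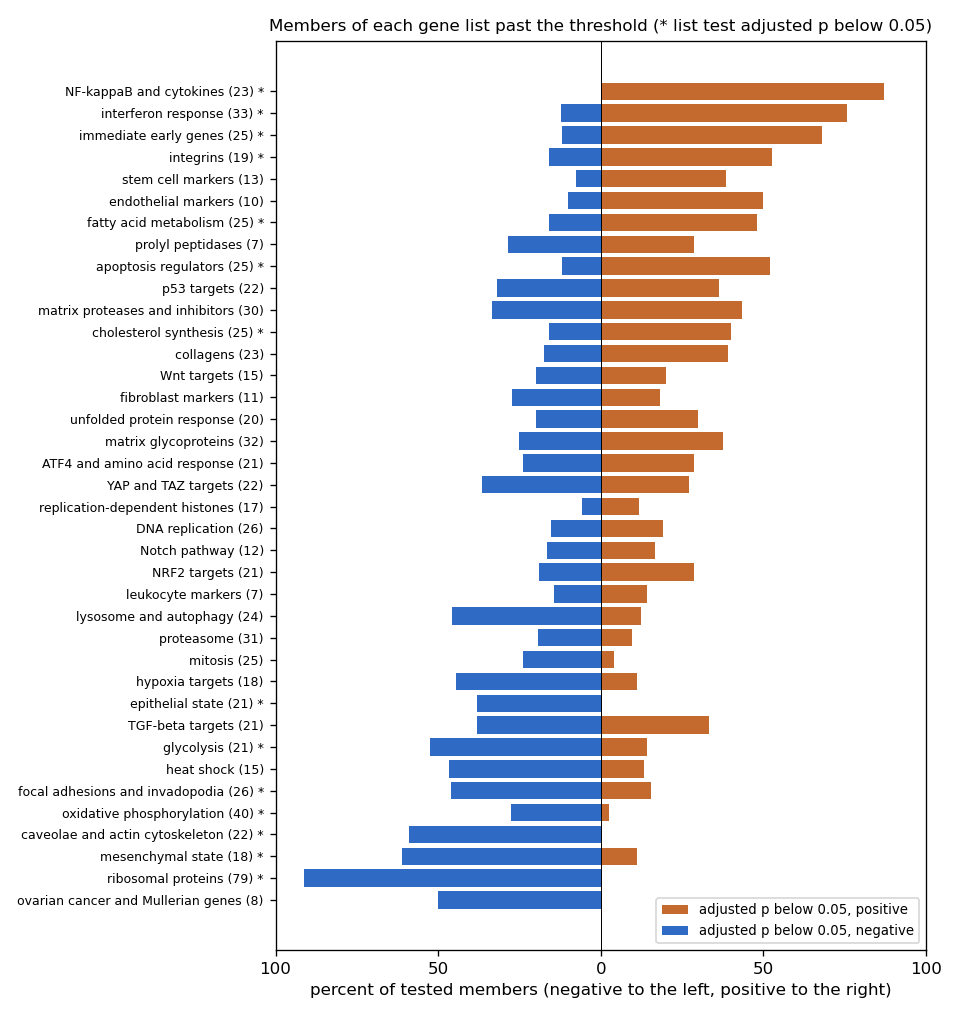
Share of the tested members of each of 38 gene lists with adjusted p under 0.05, positive to the right and negative to the left (percent; the number tested is in parentheses), ordered by median log2 fold change. Stars mark the 14 lists called by the list test; ribosomal proteins had 72 of 79 members negative and NF-kappaB and cytokines 20 of 23 positive.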

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

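A fold change without a p-value was listed for 19 genes in the authors' deposited table, so they enter no comparison. Their means ran from 24.5 to 471, above the floor of 3 counts. This result was noted because it lies in values outside the tests; no explanation for it was tested.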

How the results depend on the processing

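No paired analysis was possible because the authors' table carries no values per sample. For the same reason other count models, pseudocounts, left-out replicates, other splits of the samples and estimated correlations between genes were not run. The shrinkage, the genes with a transcript, the GC and length trend and the 3' UTR core settings were chosen after seeing the data. The number of called genes stayed within 1.5 times 7267 except with Bonferroni, at 2485 (1073 positive, 1412 negative), and with a t distribution, at 1336 (515 positive, 821 negative). Genes changed at least 2-fold numbered 1234 (569 positive) with Bonferroni, 974 (403 positive, 571 negative) with a t distribution, 1140 (486 positive) at means of at least 100, and 1122 (498 positive) in a test against 1.5-fold. They numbered 4472 (2232 positive, 2240 negative) at a 1.5-fold size threshold, and 590 were negative with the GC and length trend removed, against 750 among the same genes with a transcript before removal and 891 among all genes. Bonferroni, the t distribution and the size settings are stricter or looser by construction, and the filter holds fewer genes; the trend setting both holds fewer genes and subtracts the trend. The list test called 7 lists on log2 fold changes and 6 at a correlation of 0.05 instead of 14, and 5 lists were called in all 7 settings; the cause was not tested on fold changes, and a larger preset correlation widens the test by construction. Of 169 named genes other than FAP, 49 lost their call with a t distribution and 31 with Bonferroni. MSLN reversed from −0.30 to 0.050 with the GC and length trend removed, and the cause was not tested. FAP stayed uncalled where a value could be had. FAP lies under the floor in both groups, beside mean normalized counts that sum to 35170089. Why its count is so low was not tested.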

Other observations

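Tests chosen after the result was seen were those of FAP reads, leukocyte markers, base composition, both ways, the FAP transcript, the opposite strand, the core share and paired mates; the GC and length corrections and the first heptamer test were also added after the fold changes had been seen, with their bounds set before their own results. The FAP transcript test and some of the words below came from an incomplete recollection, from outside these data, of a published hairpin target in FAP. That recollection was not checked against a source, and the hairpin used for these samples was not compared.

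Further groups showed members on both sides. In the authors' deposited table SQSTM1, an autophagy receptor gene, was at 1.30 ± 0.11, and lysosome and autophagy genes gave 3 positive and 11 negative of 24. CCND1, the gene of cyclin D1, was at 1.52 ± 0.13, and Wnt targets gave 3 and 3 of 15. Heat shock genes gave 2 and 7 of 15, with HSPB1 at −1.32 ± 0.14. Stem cell markers gave 5 and 1 of 13, with NT5E at 1.48 ± 0.13 and CD24 at −1.34 ± 0.13. The remaining lists were not called: hypoxia targets 2 and 8 of 18, p53 targets 8 and 7 of 22, the unfolded protein response 6 and 4 of 20, the ATF4 response 6 and 5 of 21, NRF2 targets 6 and 4 of 21, Notch 2 and 2 of 12, the proteasome 3 and 6 of 31, histones 2 and 1 of 17, and matrix glycoproteins 12 and 8 of 32; 0 mitochondrial genome genes were in the table.

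The first pattern is 7267 called genes beside 2 FAP reads. GC content or length bias as the whole cause is argued against. Of the 6728 called genes with a transcript, 5452 stayed called with the GC trend removed. With the length trend removed 5520 did, and with both trends removed 5185 did. FAP had 2 reads in 1 library, and 5 libraries were without FAP reads. FAP mRNA was thus under the floor of 3 counts in both groups. This argues against loss of FAP mRNA from above the floor as the cause of the called genes. Whether loss from under the floor lies behind them stays open, because 2 reads cannot show it. Other splits of the 6 samples could not be computed, and an effect of the hairpin other than on FAP, or a difference in virus dose between the groups, may contribute; virus as such was common to both.

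The second pattern is the gene groups that moved together. With GC and length trends removed, medians were −0.54 for ribosomal proteins (from −0.63), 0.81 for interferon genes (from 0.83), 0.83 for NF-kappaB and cytokines (from 0.84) and −0.43 for caveolae and actin (from −0.47). For these lists this argues against those biases as the whole cause. Among other called lists, medians went from −0.22 to −0.096 for epithelial state, 0.56 to 0.39 for integrins and −0.27 to −0.19 for oxidative phosphorylation. Medians of immediate early genes (0.68 to 0.78), cholesterol synthesis (0.21 to 0.28) and glycolysis (−0.24 to −0.25) grew, and the rest shrank by smaller shares. The list test was not rerun with the trends removed, and for epithelial state these biases stay open. Leukocytes mixed into one side are argued against by 14.3% of leukocyte markers called positive, though only 7 were tested. Effects of the hairpin itself and of a difference in virus dose stay open and untested. For FAP knockdown the limit given for the first pattern holds here too. Loss of FAP mRNA from above the floor is argued against, and loss from under it stays open.

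The third pattern is a link between 3' UTR sequence and the negative side, set as a hypothesis of an off-target effect of a short RNA. The heptamer ACGCCCT, in the 3' UTR of 272 genes, had the largest association (z −8.49, against 5.30 as the highest of 100 shuffles), and genes with and without it differed by −0.28 in mean residual, on log2 fold changes bounded at 2 after terms for length and base composition. Its reverse complement had z 1.42, which argues against a motif read on either strand. Base composition stays open. ACGCCCT lay 5.13 SD beyond heptamers of the same bases that do not overlap it by 5 or more bases. But within its whole class it lay 4.31 SD out, which 17 of 100 shuffles reached somewhere. All 22 heptamers beyond the highest shuffle were negative with at least 5 C or G. The z of ACGCCCT was 1.34 times that of GCCCAGC, the largest heptamer not overlapping it by 5 or more bases, though they share GCCC. This was short of the 1.5 set beforehand, so a single seed stays undecided. FAP's longest transcript holds ACGCCCT 1 time, as do 10.5% of coding genes by longest transcript and 7.16% of coding transcripts. These shares lie on both sides of the bound of 10%. A hairpin directed at FAP on the positive side may be involved but was not shown. The core ACGCCC was picked after its values were seen. Among the 11421 genes of the heptamer test it was in 13.9% of called negative genes (409 of 2939). It was in 8.16% of called positive genes and 9.76% of all these genes. Most called negative genes thus lack it in the transcript used. Only 1115 genes hold the core, too few to reach the bound set for this test, so its outcome was fixed beforehand. Sites of other words were not counted.

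Among the genes of the heptamer test, the core was in 23.4% of called negative genes changed at least 2-fold (136 of 581). It was in 7.13% of called positive genes changed at least 2-fold and 8.40% of uncalled genes (477 of 5676). These shares were not adjusted for GC content or 3' UTR length. Of 26 other words looked at by hand, some lie within ACGCCCTTCA, a stretch from that unchecked recollection which the longest FAP transcript also holds. Their z were −5.39 (ACGCCCTT), −4.81 (ACGCCCTTC), −4.75 (CGCCCTTC), −2.59 (GCCCTTCA), −1.28 (the whole stretch, 5 genes) and 0.20 (CCCTTCA, which shares 4 bases with the end of ACGCCCT). Words with other bases beside the core reached similar values: CACGCCCC −5.26, CACGCCCT −4.76, TACGCCCC −4.46 and AACGCCCA −4.45. The mean residual was −0.43 for ACGCCCTA (18 genes), which departs from the stretch. Within the stretch it was −0.38 for ACGCCCTT (56 genes) and −0.55 for ACGCCCTTC (22 genes). TTACGCCCT, which begins before the stretch, had −0.58 (7 genes). These words share bases and rest on few genes, so whether the stretch stands out was not decided.

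Among genes with reads in 1 library, 725 had 2 reads and 473 had 1, and 113 had 4 against 44 with 3; the mates of read pairs may have been counted separately, in which case the 2 reads of FAP may be 1 fragment. In the library that holds the FAP reads, 84 genes had 2 reads and 65 had 1, but 3 had 4 against 8 with 3, so the pattern was not seen at 3 and 4 reads there.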
